A study of Homo sapiens with 7 samples.

How the data were processed

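The series held 7 libraries of untreated cells labelled HepG2, 4 after immunoprecipitation with an anti-m6A antibody and 3 inputs, grouped by their titles. Per the labels' protocols, total RNA was purified, selected for poly(A), broken chemically into fragments of about 100 nt, made into cDNA with random primers, size-selected on a gel at about 200 bp, amplified for 15 cycles and sequenced on an Illumina instrument. The aligner, peak caller, transcript annotation and genome build are not given in the sources used here.

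The deposited file was 1 table for the series. Per the file headers and the values, its expression column is a quantile, a fraction from 0 to 1 that ranks transcripts, and 8139 transcripts share the lowest value, 0.314. The authors' peak score is given per peak without a stated scale. It was used to rank and filter peaks and to compare medians between groups of peaks, and was treated neither as a fold nor as a logarithm. Differences of medians are therefore in units of unknown scale. Other deposited columns give each peak's position along the transcript, its exon's number and length, and its segment. TxStart is under 200 nt from the transcript start, as the values show, and 345 peaks without a segment all lay in noncoding transcripts. No column belonged to a single library, so depth per library, the agreement of libraries and a test of IP against input are not reported. The peaks themselves depend on the authors' threshold, since no score was under 2.00, and fragmentation to about 100 nt limits the resolution of positions. The headers name the cell line but do not say which libraries gave the expression quantile. Few reads may have kept a peak from being called in weakly expressed genes.

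Transcripts were matched to GENCODE release 29 by current or older symbol, chromosome, strand and exact genomic span, and by every peak lying in an exon of the stated number and length. Of 2950 transcripts matched in this way, 664 had peaks, and 649 of these had a complete coding sequence and carried 1239 peaks. The others of the 2950 had no peak, so their exons could not be checked and they were matched by symbol and span alone. Segments derived from GENCODE equalled the authors' for 99.4% of these peaks. No match shared its start coordinate with GRCh38, so the table is in another build. Only transcript sequences and structures of GENCODE were used, and printed coordinates are those of the table, with starts counted from 1. Matched transcripts had a median expression quantile of 0.789 and a median peak score of 3.16, against 0.799 and 3.15 for all transcripts with peaks.

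Peaks were shuffled 1000 times within their transcripts, leaving out 50 nt at either end because no listed position was under 51. RRACH within 50 nt was compared with windows 300 nt away on the same transcript (McNemar's exact test) and, by segment, with other positions of the same segment. Score differences were tested with 100000 permutations (10000 for 1 peak per gene and for quantiles above 0.9), and intervals of their medians came from 2000 bootstrap draws. Where 1 peak per gene was used, the peak kept was the gene's highest-scoring one, so that set is selected on score. Shares have 95% Wilson intervals. Intervals of ratios of observed to shuffled peaks divide the observed count by the central 95% of shuffled counts. They do not cover the spread of the observed count itself. Each of the 19 gene lists was tested against all other genes of the table, those without peaks included, with Fisher's exact test, and in alternatives with the Mantel-Haenszel test over bins of transcript length, of expression or of both. In all length bins, a gene's length was that of its longest GENCODE coding transcript, a stand-in for the table's own transcript. Genes without such a transcript were left out of those tests. All tests were two-sided with a threshold of 0.05, with Benjamini-Hochberg adjustment over lists or segments. Named genes are the 10 with the highest score, the 5 with the most peaks, up to 4 members of each list by score and a member without a peak (the most expressed), and all m6A machinery genes. Others were chosen after their values were seen, namely ALB, AFP, TTR, SERPINA1, HNF4A and the lineage markers. Some genes that these rules would name are not reported here. A set of 10 lineage marker lists (liver, ovarian or Müllerian epithelium, lung, intestine, melanocyte, breast, kidney, prostate, squamous epithelium and skeletal muscle) was written after the low liver genes were noticed and before the markers' own values were seen, apart from MUC16 and the plasma protein genes.

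The segment shuffle and Fisher's test of gene lists were tested on simulated data. The Mantel-Haenszel, McNemar, exon and lineage comparisons were not. For 1239 peaks placed at random, the ratio at the stop codon was 0.98, and with 20% of peaks planted there it was 2.43 against 2.43 built in. With 40-gene lists drawn from 24719 genes, 20 of 20 lists with a planted odds ratio of 5 and 0 of 100 random lists were called, with a median odds ratio of 4.29 for the planted lists. Apart from planting, all simulated genes had the same chance of a peak. The simulation therefore does not cover lists that differ in expression or length. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used. The 2 entries of ribosomal RNA with placeholder coordinates were left out of the gene lists.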

Results

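N6-methyladenosine (m6A), the commonest internal modification of messenger RNA, was mapped across the transcriptome of untreated cells labelled HepG2, a human hepatocellular carcinoma line. Polyadenylated RNA was broken into fragments of about 100 nt and precipitated with an antibody against m6A. The series held 4 immunoprecipitated (m6A-IP) and 3 input libraries, and the question was which sequences carry the mark. The deposited values were 1 table for all 7 libraries together, with an expression quantile for each transcript and the position, exon, segment and score of each peak. No value per library was given, so library depth is unknown and replicate error, or a test of IP against input, could not be had. Intervals and p-values below cover counting and positional chance in this table alone, since neither peaks nor genes are replicates.

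The table listed 25918 transcripts of 24721 gene symbols, 19965 of them coding, and 7240 transcripts (27.9%) had at least 1 peak. These carried 12769 peaks, a mean of 1.76 per transcript with a peak. There were 4047 transcripts with 1 peak, 1887 with 2, 752 with 3 and 554 with 4 or more. Peak scores, which are the authors' own, ran from 2.00 to 7.91 with a median of 3.15. The highest score belonged to DOCK5, a guanine nucleotide exchange factor for Rac (chromosome 8, 25098204 to 25326536, plus strand), at position 6102 of the transcript in the 3' UTR part of exon 52. The next were ITGA6, the integrin alpha-6 subunit (7.73, near the stop codon in exon 25, chromosome 2, 173000560 to 173079427), and MICALL2, a Rab effector (7.63, near the stop codon in exon 17, chromosome 7, 1440521 to 1465635). OXSR1, a stress-responsive kinase, scored 7.49, PDCD11, a ribosome biogenesis factor, 7.43, and IL6ST, the shared receptor subunit of interleukin-6 cytokines, 7.33. The cell cycle transcription factor E2F3 scored 7.31, the spliceosomal helicase DDX23 7.30, the phosphodiesterase PDE7A 7.28 and the m6A reader YTHDF3 7.27. Of these 10 genes, 6 had the peak near the stop codon, 3 in the 3' UTR and 1, YTHDF3, in the coding sequence. Coordinates are as the table gives them, in a genome build not given in the sources used here, and positions count from the transcript's 5' end.

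The genes with the most peaks encoded very large proteins. MLL2 (now KMT2D), a histone H3 lysine 4 methyltransferase (chromosome 12, 47699025 to 47735374, minus strand), and the membrane mucin MUC16 (chromosome 19, 8820520 to 8953018, minus strand) had 14 peaks each. AHNAK, a giant scaffold protein, AKAP13, a kinase anchor, and MLL (now KMT2A), a further histone methyltransferase, had 12 each. In 4 of the 5 most peaks lay in a single long exon. All 12 peaks of AHNAK lay in exon 5 (18173 nt), 9 of the 14 of MUC16 in exon 3 (21693 nt), 7 of the 12 of AKAP13 in exon 7 (3178 nt) and 7 of the 12 of MLL in exon 27 (4249 nt). MLL2 was more spread, with 6 of 14 in exon 39 (2790 nt). Across 649 transcripts matched to GENCODE, peak number rose with transcript length (Spearman rho across transcripts 0.44, permutation p = 0.0001, the smallest that 10000 permutations can give). Median length was 2600 nt for the 347 transcripts with 1 peak and 5849 nt for the 74 with 4 or more.

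Peaks gathered around the stop codon and at the start of the transcript. By the authors' annotation of 12424 peaks, 36.6% lay in the coding sequence (95% Wilson interval 35.8 to 37.4%), 27.6% around the stop codon (26.8 to 28.4%) and 20.5% in the 3' UTR (19.8 to 21.2%). A further 12.5% lay within 200 nt of the transcript start (11.9 to 13.1%) and 2.78% in the rest of the 5' UTR (2.51 to 3.09%). The stop codon segment was the region within 200 nt of the stop codon, leaving out positions under 200 nt from the transcript start. Among the 1239 peaks of the 649 matched transcripts, it held 313 peaks against 152 when the same peaks were shuffled within their transcripts, a ratio of 2.06. The transcript start held 121 against 58.8, also a ratio of 2.06, while the coding sequence held 0.84 and the 3' UTR 0.67 times the shuffled number (permutation p = 0.0020 for each, the smallest two-sided value that 1000 shuffles give). The remaining 5' UTR, with 31 peaks against 34.8, did not differ (permutation p = 0.56). These shuffles, and those around the codons below, ran over the whole transcript without regard to exons. Internal exons under 200 nt held only 0.44 peaks per 10000 nt, against 10.3 in those of 400 nt and over. What exon length and splice junctions contribute to the stop codon and coding sequence ratios was not tested. Among peaks with a score above the median the excess at the transcript start was smaller, at 1.43 (permutation p = 0.050). The start excess was carried by strongly expressed transcripts, with ratios of 1.30, 1.18 and 3.19 from the lowest to the highest expression tertile (permutation p = 0.29, 0.48 and 0.0020).

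**Figure D1:**
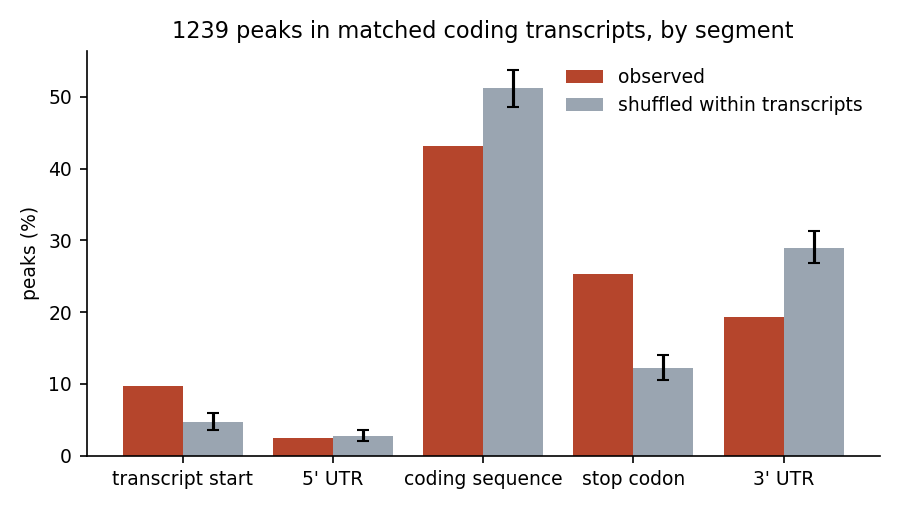
Percent of the 1239 peaks of matched coding transcripts in each transcript segment, observed (red) and after shuffling within transcripts (grey; bars are means and whiskers the central 95% of 1000 shuffles). The stop codon and the transcript start each held 2.06 times the shuffled number.

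Around the stop codon the excess grew as the window narrowed, from 1.57 within 400 nt to 2.07 within 200 nt and 2.57 within 100 nt (permutation p = 0.0020 each). Peaks with a score above the median were 2.77 times as frequent as shuffled within 200 nt of the stop codon. Near the start codon the ratio was 1.39 within 200 nt (permutation p = 0.0020). It fell to 1.09 within 400 nt (permutation p = 0.17) and to 1.09 among peaks with a score above the median (p = 0.55). In a larger set matched with a tolerance of 10 nt (1978 peaks) it was 1.21 within 400 nt (permutation p = 0.0020).

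Whether a transcript had a peak went with its expression. No peak was listed in the 8139 transcripts tied at the lowest expression quantile (0.314). Of coding transcripts, 3.94% had a peak at quantiles of 0.4 to 0.5, 28.4% at 0.5 to 0.6, 52.1% at 0.6 to 0.7 and 71.5% (69.7 to 73.2%) at 0.8 to 0.9. The share was 61.5% (57.1 to 65.7%) above 0.98. Start peaks rose steadily with expression, from 3.56% of the peaks of coding transcripts at quantiles of 0.5 to 0.6 (2.50 to 5.03%) to 34.4% above 0.98 (30.1 to 38.8%). The share around the stop codon stayed between 26.3% and 28.5% over the same quantiles. Noncoding transcripts above the lowest quantile had a peak less often, 248 of 2504 (9.90%) against 6990 of 15273 coding ones (45.8%). Within bins of expression the Mantel-Haenszel odds ratio was 0.31 (95% interval 0.26 to 0.36), against 0.13 without bins. No bins of transcript length were used for this comparison. Small nucleolar RNAs had no peak (0 of 57 expressed SNORD and 0 of 50 expressed SNORA genes). No listed peak position in the table was under 51, and the RNA was selected for poly(A) and fragmented. Very short transcripts therefore had little room for a listed peak, and no conclusion is drawn from these zeros. What short transcripts contribute to the odds ratio of noncoding transcripts was not tested. MALAT1, an abundant nuclear RNA (chromosome 11, 65022410 to 65030999), was the top-scoring member of the long noncoding list with 3 peaks and a score of 6.05.

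**Figure D2:**
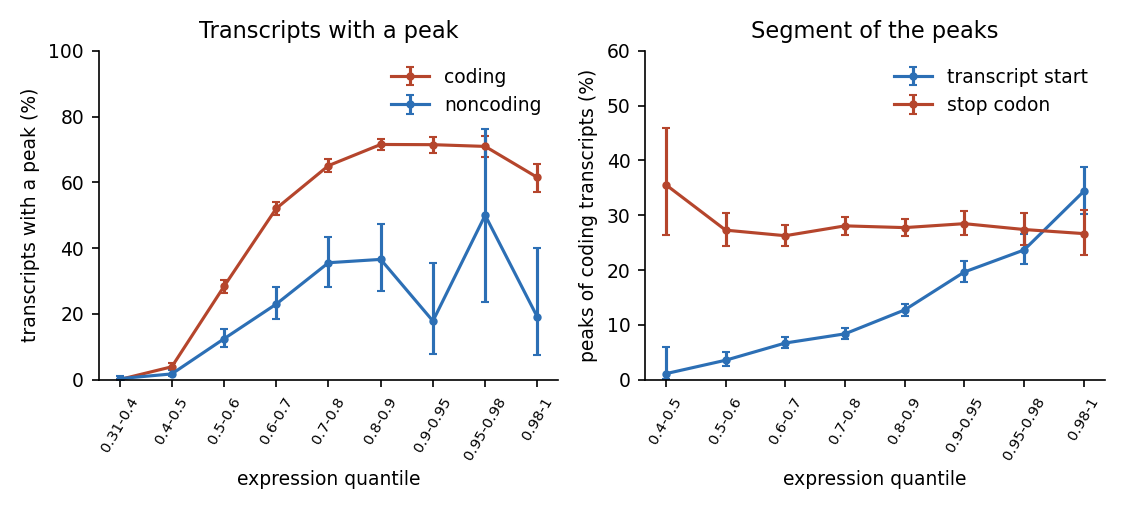
Left, percent of coding (red) and noncoding (blue) transcripts with a peak by expression quantile. Right, percent of the peaks of coding transcripts at the transcript start (blue) and around the stop codon (red). Points are shares and whiskers 95% Wilson intervals. The start share climbed from 3.56% at 0.5 to 0.6 to 34.4% above 0.98, and the stop codon share did not.

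The m6A consensus RRACH (R is A or G, H is A, C or U) marked peaks in every segment but the transcript start. Of 1192 peaks with a control window, 90.1% had RRACH within 50 nt (88.3 to 91.7%), against 75.9% of windows 300 nt away on the same transcript (McNemar's exact test, two-sided, p = 5.58e-20, 260 against 91 discordant pairs). GGACU was found near 31.0% of these peaks and 9.40% of control windows. Among peaks outside the transcript start it was the most enriched of the 12 RRACH pentamers, 3.56-fold over the same transcripts as a whole. AGACU followed at 2.29-fold and GGACA at 2.17-fold, and AAACA was the only one depleted, at 0.77-fold. With U also allowed as first base (DRACH), 93.4% of peaks and 84.5% of control windows had the motif within 50 nt. That excess was 8.89 percentage points (McNemar's exact p = 5.52e-12, n = 1192). Within 100 nt, where 96.6% of control windows had DRACH, the excess was 1.98 points (McNemar's exact p = 0.0038, n = 1060). The RRACH excess within 100 nt was 5.28 points. Above the median score the DRACH excess within 100 nt was 1.55 points and was not called (McNemar's exact p = 0.064, n = 581). RRACH was found near 94.6% of stop codon peaks, 92.9% of coding sequence peaks, 92.0% of 3' UTR peaks and 86.7% of 5' UTR peaks, in each case above other positions of the same segment (73.3%, 74.98%, 72.5% and 66.0%; permutation p = 0.0040 for the 5' UTR and 0.0020 for the others). Start peaks had it in 64.5% of 121 cases (55.6 to 72.4%), against 62.6% at the same positions of transcripts without a start peak (permutation p = 0.73).

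**Figure D3:**
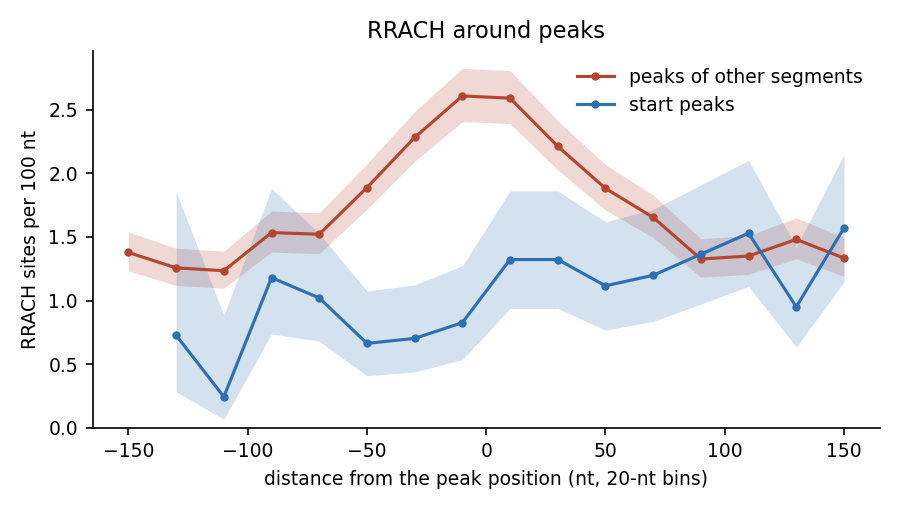
RRACH sites per 100 nt by distance from the peak position, in 20-nt bins, for start peaks (blue) and the peaks of other segments (red). Bands are 95% Wilson intervals. Peaks of other segments rose to 2.61 sites per 100 nt in the bin just upstream of the peak position, and start peaks had 0.83 there.

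Scores followed position as well. Stop codon peaks had a median score of 3.45, which was 0.31 above coding sequence peaks (95% bootstrap interval 0.23 to 0.38). Start peaks had a median of 2.73, which was 0.42 below them (difference -0.42, interval -0.47 to -0.36). The difference was -0.86 with 1 peak per gene and -0.19 above an expression quantile of 0.9. For stop codon and start peaks, the permutation p adjusted over 4 segments by the Benjamini-Hochberg method was 2.0e-05 (1.0e-05 before adjustment, the smallest that 100000 permutations can give). The 3' UTR differed by 0.073 (adjusted permutation p = 0.030), but was not called with 1 peak per gene (0.074, adjusted permutation p = 0.25) or on ranks (adjusted permutation p = 0.082). The 5' UTR differed by -0.15 (adjusted permutation p = 0.037), and by -0.50 with 1 peak per gene (adjusted permutation p = 0.00020). Above an expression quantile of 0.9 the 5' UTR difference was 0.054 (adjusted permutation p = 0.60) and that of the 3' UTR 0.16 (adjusted permutation p = 0.012). With 1 peak per gene, the stop codon difference shrank to 0.029 (adjusted permutation p = 0.70). The peak kept was the gene's highest-scoring one, so the values with 1 peak per gene come from a set selected on score. The median score of coding sequence peaks was 3.72 in that set, against 3.14 for all peaks. Peaks with RRACH within 50 nt scored 0.30 higher than those without (interval 0.16 to 0.45, permutation p = 0.0081, 1116 against 123 peaks), and 0.58 higher with 1 peak per gene (interval 0.26 to 0.79).

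Internal exons carried peaks mainly where they were long. Of 349 peaks in internal exons of matched transcripts, 284 (81.4%) lay in exons of at least 400 nt, against 45.2% after shuffling within those exons, a ratio of 1.80 (permutation p = 0.0020). The density was 0.44 peaks per 10000 nt in exons under 200 nt, 1.73 from 200 to under 400 nt and 10.3 at 400 nt and over, while RRACH sites were equally frequent, at 1.56, 1.53 and 1.57 per 100 nt. Within the long exons peaks avoided the splice junctions. Positions under 50 nt from a junction held 4 peaks against 29.1 shuffled (ratio 0.14, permutation p = 0.0020), those from 50 to under 100 nt 18 against 29.5 (ratio 0.61, p = 0.020), and those from 100 to under 150 nt 32 against 29.5 (ratio 1.09, p = 0.67).

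**Figure D4:**
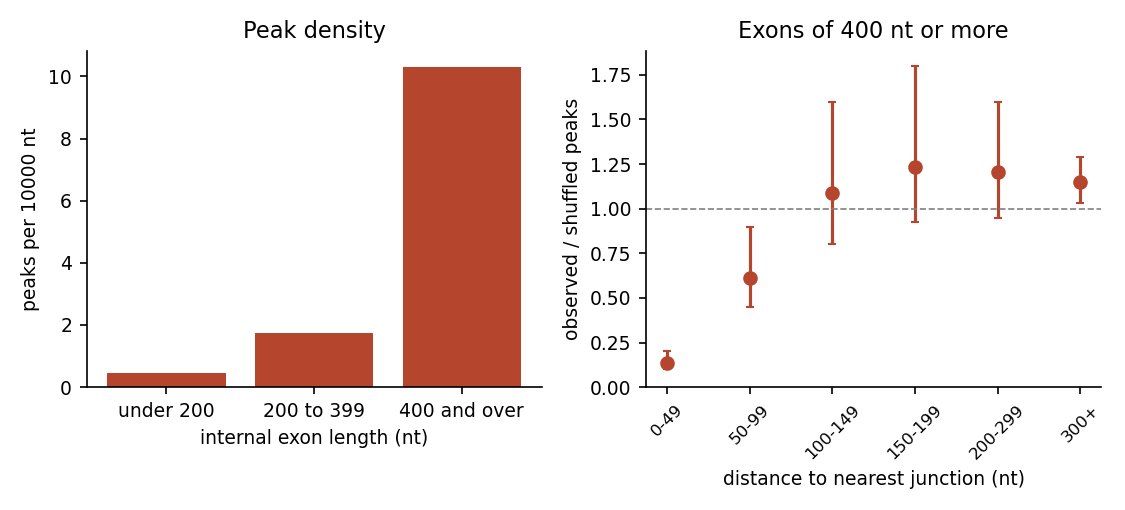
Left, peaks per 10000 nt of internal exon by exon length, for 349 peaks. Right, observed over shuffled peaks by distance to the nearest splice junction within internal exons of 400 nt or more (284 peaks, whiskers from the central 95% of 1000 shuffles, dashed line at 1). Density rose from 0.44 to 10.3 per 10000 nt, and the ratio was 0.14 next to junctions.

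Of 19 gene lists fixed before the data were examined, 10 held a higher and 3 a lower share of genes with a peak than the other genes of the table (about 29.1%; two-sided Fisher's exact test, adjusted over the lists). Of 45 chromatin modifiers, 39 (86.7%) had a peak (Fisher's adjusted p = 2.48e-14), among them the remodeller CHD7 (6 peaks, top score 6.26), the histone demethylase UTX, now KDM6A (5.98), the acetyltransferase CREBBP (5.96) and the methyltransferase NSD1 (7 peaks, 5.92), but not SMARCC1. Of 40 immediate early genes, 33 did (82.5%, Fisher's adjusted p = 3.46e-11). They included MYC, a growth-promoting transcription factor (score 6.76 around the stop codon in exon 3, chromosome 8, 128817498 to 128822855), the matricellular protein CYR61 (5.64), the AP-1 subunit FOSB (5.36, in the 5' UTR) and IER2 (5.17), but not PPP1R15A. Of 36 genes of Wnt, Notch and TGF-beta signalling, 28 did (77.8%, Fisher's adjusted p = 1.33e-08), with SMAD2, a TGF-beta signal transducer, at 6.68, the receptor NOTCH2 at 6.64 with 6 peaks, the Wnt effector CTNNB1 at 5.68 and the ligand JAG2 at 5.43, but not TCF7L2. Within bins of expression these 3 lists were the only ones still called higher, with Mantel-Haenszel odds ratios of 3.22, 3.44 and 3.28 (n = 45, n = 40 and n = 35 expressed genes, adjusted p = 0.028 each). Within bins of expression and transcript length together no list was. The odds ratios were then 1.60 for chromatin modifiers and 1.74 for signalling genes, but 2.87 for immediate early genes (interval 1.16 to 7.08, n = 40, p = 0.033 before and 0.20 after adjustment).

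The m6A machinery itself was marked in 16 of 20 genes (80.0%, Fisher's adjusted p = 1.13e-05). The writers METTL3 (2 peaks, top score 3.01), WTAP (5.25), METT10D, now METTL16 (5.24), ZC3H13 (4.77), KIAA1429, now VIRMA (3.72), RBM15 (3.21), RBM15B (4.35) and CBLL1 (2.26) had peaks. So did the readers YTHDF1 (4 peaks, 2.79), YTHDF2 (4.18), YTHDF3 (7.27), YTHDC1 (2.78), IGF2BP1 (3.04), IGF2BP2 (3.94), IGF2BP3 (2.90) and HNRNPA2B1 (4.02). The demethylases FTO and ALKBH5 had none, nor did YTHDC2 and HNRNPC, at expression quantiles of 0.728, 0.968, 0.668 and 0.924. Other lists above the rest were aminoacyl-tRNA synthetases (16 of 20, Fisher's adjusted p = 1.13e-05; CARS 5.61, HARS 5.53, not WARS), cell cycle genes (33 of 49, 1.60e-07; E2F3 7.31, the helicase subunit MCM2 6.80, not MCM4), splicing factors (22 of 37, 0.00039; SF3B3 4.71, SRRM2 4.55 with 5 peaks, not HNRNPD), cholesterol genes (16 of 27, 0.0017; HMGCS1 4.89, SQLE 4.47, not SREBF2) and the proteasome (18 of 31, 0.0017; PSMD3 4.09, PSMD2 3.90, not PSMC5). All of these 6 calls, the m6A machinery included, ended within bins of expression.

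Genes of the respiratory chain and ribosome stood apart. Of 66 nuclear genes of oxidative phosphorylation, 32 had a peak (48.5%, Fisher's adjusted p = 0.0017), led by the ATP synthase subunit ATP5B (4.86) and the complex I subunits NDUFS8 (4.54) and NDUFS5 (4.28), each at the transcript start, while COX5B had none. Of their 32 peaks, 27 were start peaks (84.4%, Mantel-Haenszel odds ratio 15.98 within bins of expression, interval 6.17 to 41.4, n = 32, adjusted p = 3.33e-14 over 15 lists). Within bins of expression the list turned from higher to lower (odds ratio 0.47, n = 66, adjusted p = 0.014). It was not called within bins of expression and length together (0.67, interval 0.41 to 1.12, n = 66, adjusted p = 0.46), and was higher within bins of length alone (2.91, n = 66, adjusted p = 5.70e-05). Proteasome and cell cycle genes were also rich in start peaks, with 13 of 21 and 16 of 43 (n = 21 and n = 43 peaks, adjusted p = 0.00059 and 0.011). Chromatin modifiers (8 of 150) and immediate early genes (5 of 64) were poor in them (n = 150 and n = 64 peaks, adjusted p = 0.015 and 0.031). Around the stop codon lay 30 of the 64 peaks of immediate early genes and 24 of the 150 of chromatin modifiers, more and fewer than in other genes (n = 64 and n = 150, adjusted p = 0.011 each). These segment shares were compared within bins of expression but not of transcript length. Median lengths were 1260 nt for oxidative phosphorylation, 1581 for the proteasome, 3330 for cell cycle, 3053 for immediate early genes and 7061 for chromatin modifiers. What length contributes to these shares was not tested.

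Cytosolic ribosomal protein genes had a peak in 8 of 76 cases (10.5%, Fisher's adjusted p = 0.00040) despite a median expression quantile of 0.994. The exceptions included RPS4X (4.26), RPL13 (4.26), FAU (3.79) and RPL28 (2 peaks, 2.81), and RPL8 had none. The share remained lower within bins of expression and length (odds ratio 0.058, interval 0.024 to 0.138, n = 76, adjusted p = 1.40e-14). The length binned was that of the longest GENCODE coding transcript (median 1170.5 nt for this list), so the table's own transcript lengths were not matched. Replication-dependent histones, whose messages lack poly(A) tails, had a peak in 6 of 32 genes (18.8%, Fisher's adjusted p = 0.27), among them HIST2H2BE (3.00) and HIST1H3D (2.90) but not HIST1H4E. Within bins of expression they were called lower (odds ratio 0.11, n = 30 expressed genes, adjusted p = 5.25e-07), and less so within bins of expression and length (0.28, adjusted p = 0.041). Within bins of length alone they did not differ (1.09, n = 32, adjusted p = 0.96). Glycolysis genes (10 of 22, Fisher's adjusted p = 0.13; PFKFB3 5.64, HK2 4.68, not GAPDH) and long noncoding RNAs (5 of 17, adjusted p = 1.0) were not called.

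**Figure D5:**
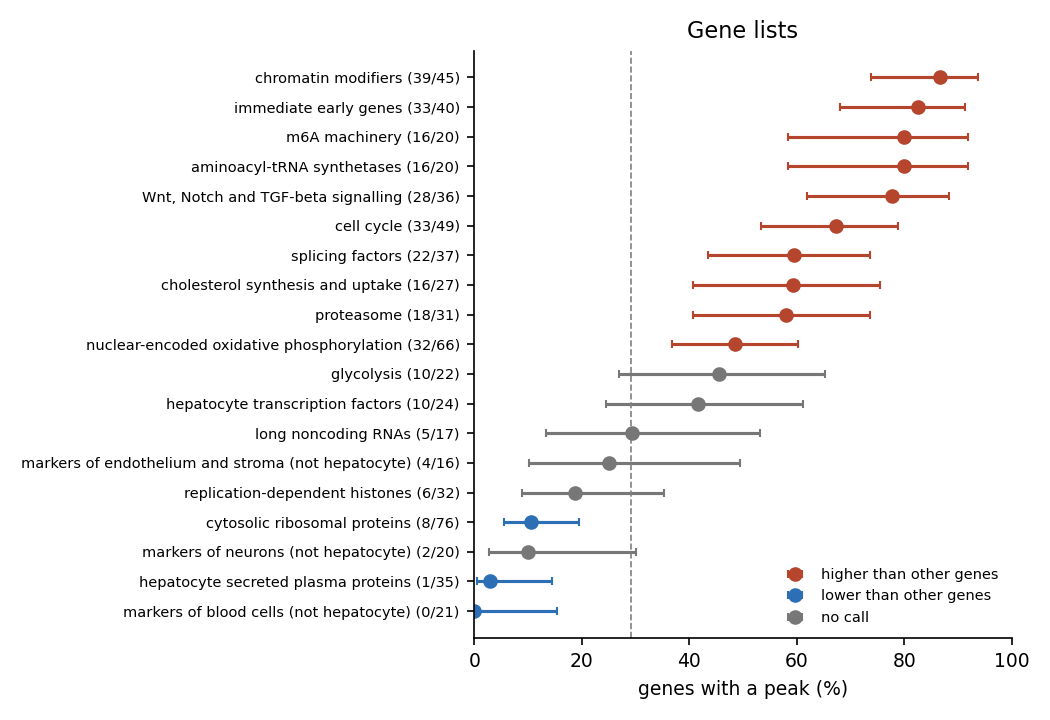
Percent of the genes of each list with at least 1 peak, with 95% Wilson intervals and counts in brackets. Red lists were higher and blue lists lower than the other genes (dashed line, 29.1%), and grey lists were not called.

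The liver genes of the table did not follow the cell line's label. Of 35 plasma protein genes that hepatocytes secrete, 1 had a peak (2.86%, Fisher's adjusted p = 0.00034), the complement component C3 (score 2.61, expression quantile 0.960). Within bins of expression this call ended, though the odds ratio stayed low at 0.13 (n = 13 expressed genes, adjusted p = 0.44), and that of the blood cell markers (0 of 10 expressed genes) ended too. Of these genes 22 were tied at the lowest expression quantile, among them ALB (albumin), AFP (alpha-fetoprotein), TTR (transthyretin) and SERPINA1 (alpha-1-antitrypsin), and the next after C3 was FN1 (fibronectin) at 0.763, without a peak. Hepatocyte transcription factors had a peak in 10 of 24 genes (41.7%, Fisher's adjusted p = 0.22), including CEBPA (5.53), PPARA (5 peaks, 4.90), GATA6 (4.32) and FOXA1 (4.07), but HNF4A had none, at 0.509. Markers of other cell types were mixed. Blood cell markers had no peak in 21 genes (Fisher's adjusted p = 0.0017), and CD68 was the most expressed of them at 0.879. Neuronal markers (2 of 20, NEFH 4.49 and GRIN1 3.83; Fisher's adjusted p = 0.11, though called lower within bins of transcript length with an odds ratio of 0.14) and endothelial or stromal markers (4 of 16, adjusted p = 1.0) were not called. The matrix proteoglycans LUM (3 peaks, top score 4.20) and DCN (2.29) stood at quantiles of 0.9005 and 0.924.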

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

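The test of failed expression estimates was written after its values were seen, the test of other lineages after the liver pattern was noticed but before its values were seen, and the others before theirs, except that the lower expression tertiles were pooled after each had been seen. The table held 2 ribosomal RNA entries outside the gene comparisons, each with a peak. The 18S entry (NR_003286) had a peak at position 1764 of 1869 with a score of 4.64, and the 28S entry (NR_003287) at position 4235 of 5070 with a score of 2.57. They were singled out because they lie outside the messenger RNA measurement, and no control samples could be compared.

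The first pattern is the peaks at the transcript start. An edge effect of peak calling should also raise the 3' end, where the ratio of observed to shuffled peaks at the same distance was 0.93 (permutation p = 0.61), against 2.05 at the 5' end. Greater depth in strongly expressed genes predicted no excess in the lowest expression tertile. The ratios were 1.30 (permutation p = 0.29), 1.18 (p = 0.48) and 3.19 (p = 0.0020) from the lowest to the highest. The lower tertiles pooled gave 1.23 (interval from the spread of the shuffles alone, 0.91 to 1.79). Depth may therefore account for the pattern, and a true rise with expression was not told apart from it. Methylation of the adenosine next to the cap, which the antibody can bind and which needs no RRACH, predicts no motif excess, and the excess was 1.86 percentage points at start peaks against 17.9 in the coding sequence, which is consistent with it, though 121 start peaks do not show the excess to be absent. The annotated first base, examined without a prediction, was A in 35.5% of start-peak transcripts, against 25.2% of other transcripts with a peak (Fisher's exact p = 0.024) and 29.6% of other matched ones in the expression range of peaks (p = 0.18).

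The second pattern is the peaks in long internal exons. RRACH density does not account for it, as the ratio was 1.81 when peaks were shuffled over RRACH adenosines alone. At positions at least 100 nt from any junction the ratio fell from 1.80 to 1.06 (interval 1.03 to 1.10, permutation p = 0.0020), where 1.14 was the highest possible. It was 1.05 for exons of at least 300 nt (permutation p = 0.0020). For exons of at least 1000 nt it was 1.05 and not called (interval 0.99 to 1.11, permutation p = 0.10). Loss at junctions is therefore argued against only as the whole cause, and not with the 1000-nt cut. A depletion reaching no further than the fragment length may account for most of it, since positions from 100 to under 200 nt from a junction held 0.92 times the shuffled number (permutation p = 0.40). Whether reads were lost at junctions or methylation is excluded there was not tested, and no biological explanation was tested.

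The third pattern is the liver genes at the lowest expression quantile. Of 20 liver genes, 11 were at the lowest value, none was above 0.8 and none had a peak. This list was written after low liver genes were noticed and holds plasma protein genes whose values had been seen. Outside it, C3 (0.960) and the hepatocyte transcription factors CEBPA (0.843) and FOXA1 (0.834) were above 0.8, each with a peak. A failure across the whole expression column is argued against, since 0 of 127 ribosomal protein, proteasome and aminoacyl-tRNA synthetase genes were at the lowest value (median quantile 0.980). Estimates that failed for liver genes alone could not be seen in these genes, and the criterion was written after its values were known. Cells of another lineage than the label names could give this pattern, but none of 9 other lineage lists stood out, the highest being melanocyte at percentile 20.6 of 10000 random lists. By the criterion written beforehand that value argues against another lineage; it is left undecided instead, a choice made after the value was seen, because a lineage outside these 9 lists would give the same value and no list of known outcome was run. Loss of liver genes in correctly labelled cells was not tested, nor was any biological explanation.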

How the results depend on the processing

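The alternatives with a span within 10 nt, with expression or RRACH number, with expressed genes alone, or without start peaks were chosen after seeing the data. No paired analysis was possible because the table has no value per library. For the same reason the IP against input test with its scalings, filters, pseudocounts and replicate block, the agreement of libraries and leaving out replicates were not run, and neither were a fold of at least 4 or log2 fold, since the score is not stated to be a fold. Of 234 alternatives over 43 results, 158 kept their side of the threshold, or for shares, means and counts of lists stayed near the main value. Called results among them kept their direction, while some uncalled ones turned. Among the 234, ratios of observed to shuffled peaks at the stop codon, transcript start, coding sequence and 3' UTR kept direction and side. The motif excess and long-exon ratio did too, but not in all settings given above. Segment shares moved beyond their intervals, except the coding share above the median score (36.3%). Above the median score the start, 5' UTR, stop codon and 3' UTR shares were 6.98, 2.44, 32.7 and 21.5%. With 1 peak per gene the start, 5' UTR, coding, stop codon and 3' UTR shares were 14.8, 2.50, 29.8, 35.3 and 17.6%, and on the reference annotation of matched transcripts 9.77, 2.50, 43.1, 25.3 and 19.4%. The start codon ratio lost its call within 400 nt (1.09, permutation p = 0.17) and above the median score (1.09, p = 0.55), but not within 400 nt in transcripts matched within 10 nt (1.21). The score difference from the coding sequence lost its call at the stop codon with 1 peak per gene (0.0290), and in the 3' UTR with 1 peak per gene (0.0738) and on ranks (88.1 mean ranks, permutation p = 0.082). It was larger with 1 peak per gene at the start (-0.86) and in the 5' UTR (-0.50), as was the RRACH difference (0.58). In the 5' UTR it reversed above expression quantile 0.9 (0.0540, permutation p = 0.60). Merging fragments that overlap left 12728 of 12769 peaks. The cause was not tested for any of these. From 10 lists called higher, 4 were with at least 2 peaks, 6 among expressed genes, 3 in expression bins (also 3 above the median score) and 0 in expression and length bins, where immediate early genes still had an odds ratio of 2.87 (interval 1.16 to 7.08). Lists called in the main test reversed as follows. Oxidative phosphorylation had odds ratios of 0.60 above the median score, 0 with at least 2 peaks (0 of 66 genes), 0.47 in expression bins, 0.67 in expression and length bins and 0.23 in expression bins above the median score. The proteasome had 0.72 with at least 2 peaks, 0.64 in expression bins, 0.83 in expression and length bins and 0.37 in expression bins above the median score. In expression bins cholesterol genes had 0.97 and splicing factors 0.77, and in expression and length bins cholesterol genes had 0.87, cell cycle genes 0.97 and splicing factors 0.51. Of these reversals only those of oxidative phosphorylation with at least 2 peaks, in expression bins and in expression bins above the median score were themselves called. Of the 149 alternatives for single lists, 98 kept their side of the threshold, 30 lost their call, 7 gained one and 14 turned the direction of a called list. Among the 98, uncalled lists turned too, namely glycolysis (down to 0.47), long noncoding RNAs (down to 0.28), histones (1.09), stromal (1.17) and neuronal markers (1.06). Ribosomal proteins stayed lower in length bins (0.36), RRACH number bins (0.33) and expression bins (0.064). Depth per library is unknown, so weakly expressed genes without a peak cannot be called unmethylated.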

Other observations

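These tests were chosen after seeing the data. Symbol stems with at least 20 expressed genes gave 57 families, and all but SNORD and SNORA, which had no value there, were compared within bins of expression and transcript length. Zinc finger genes of the ZNF family, mostly transcription repressors, had a peak in 218 of 431 expressed members (50.6%) at a median expression quantile of 0.566 (odds ratio 2.66, n = 431, adjusted p = 1.21e-10). The related ZBTB family, zinc finger proteins with a BTB domain, had one in 34 of 36 (94.4%, n = 36, adjusted p = 6.57e-05). Lower within these bins were RPL, RPS and HIST genes and the translation initiation factors of the EIF family. For EIF the Mantel-Haenszel odds ratio was 0.36 (interval 0.20 to 0.63, n = 57, adjusted p = 0.0039), with a peak in 25 of 57 (43.9%). Without bins, 48.1% of the 14010 expressed genes with a length had a peak. The ZNF and EIF shares lay near that value, so the shares alone do not show either difference.

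Median expression quantiles of the 10 lineage lists were 0.314 for liver, lung, intestine, kidney and skeletal muscle, 0.317 for breast, 0.337 for prostate, 0.345 for ovarian or Müllerian epithelium, 0.433 for squamous epithelium and 0.447 for melanocyte. Single members stood higher, namely SFN, an epithelial 14-3-3 protein, at 0.991 and MSLN (mesothelin), with 3 peaks, at 0.968. MUC16 was at 0.667, the lung and thyroid factor NKX2-1 at 0.696, MITF, a melanocyte factor, at 0.703 and SOX17 at 0.648, each with at least 1 peak. The folate receptor FOLR1 was at 0.672 without a peak. H19, a fetal imprinted RNA, was at 1.00, with a peak scored 2.56.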
